A study of Rattus norvegicus with 9 samples.

How the data were processed

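RNA was extracted with Trizol and sequenced as stranded poly(A)-selected libraries, per the labels' protocols, from rat adipose-derived stromal cells grown in DMEM/F12 with 10% fetal bovine serum. Reads were aligned with HISAT2 to the Rnor_6.0 genome, per the submitters' processing notes. The HISAT2 version, the read counter, its strand setting and the tool that made the FPKM values are not given in the sources used here, so the assignment of reads to overlapping or antisense genes is uncertain. The deposited table gives, for each of 9 libraries, a whole-number count per gene that had not been normalised, per the file headers and the values. It also gives an FPKM per gene made by the authors, which was used for the implied gene length and for an alternative fit. The table held 21923 genes by symbol and Ensembl identifier. Of these, 27 had date-like symbols, and the identifier was used for them. Gene positions were not used here, as the reference table is of another assembly (GRCr8) and served for synonyms alone.

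Libraries were grouped as Con, Vitro and Vivo by their labels, 3 in each. The host of the Vivo cells was a mouse and the alignment was to the rat genome, so reads from host cells may align less often than reads from rat cells. Total counts were 17484607 to 18355242 per library, and the 10 most abundant genes took 10.9% to 16.7% of them. A count of 0 allows up to 3 counts, which is 0.163 to 0.172 CPM per library before scaling. A fold against a group with no count was computed with 3 counts over the group as a floor, and with 1 to 3 counts a ratio was given with its exact 95% binomial interval.

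Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 12364, and libraries were scaled by TMM. One quasi-likelihood fit of the 3 groups over all 9 libraries, with 6 residual degrees of freedom, was tested for the 3 pairwise contrasts and for any difference among the groups, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.231. Log2 fold changes are edgeR's with its default prior count, and their SE is the absolute log2 fold change over the square root of the F statistic. Principal components and correlations were computed on log2 CPM with a prior count of 2. Wilson intervals were used for shares of counts. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

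Choices were made before the data were examined except where stated. They fixed 32 gene lists with 508 symbols, of which 487 were found in the table by symbol and 1 more through the reference table, and 358 were measured after filtering. Ccnb2, Cdkn2d, Lepr, Col6a3, Egln1, Znrf3, Nos2, Ier2, Pecam1 and Robo4 were among the symbols not analysed here. The 27 lists with at least 3 measured genes were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, and adjusted over the lists within each comparison. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Of 29 calls with the preset correlation, 28 were lost with the estimated one. Genes were named by a rule: per comparison, up to 8 rises and 8 falls past the threshold with no overlap between libraries, at least 5 CPM in the higher group and an established symbol; up to 4 called members per list, or the most abundant member where none was called; and 20 fixed genes.

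The fit, and camera with its preset correlation, were tested on counts simulated for 12364 genes, with a mean common to all libraries and the real library sizes. Genes were drawn independently of each other. The simulation therefore cannot show how list calls or false calls behave where genes move together. Of 100 genes changed 2-fold, 52%, 50% and 44% were recovered for Vivo against Con, Vitro against Con and Vivo against Vitro, and of 100 changed 4-fold, 87%, 91% and 88%, with 7, 8 and 4 false calls. Alternatives were DESeq2-style size factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, fits to 2 groups alone and a minimum change of 2-fold. Alternatives chosen after seeing the data were limma with sample quality weights, offsets that removed each library's trend with gene length, and limma on log2(FPKM + 1). Deposited pathway annotation was also tested with camera after seeing the data. Other splits of the libraries were refitted, 10 for each pair of groups and 100 drawn for the 3 groups.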

Results

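Poly(A)-selected RNA was sequenced from adipose-derived stromal cells (ADSCs), plastic-adherent mesenchymal cells obtained here by collagenase digestion of inguinal fat from GFP-transgenic rats. The 9 libraries fell into 3 groups of 3. Con libraries came from cells at passage 4. Vitro libraries came from passage 4 cells kept in ordinary culture and collected when the third group was collected. Vivo libraries came from passage 4 cells injected into the adipose tissue of nude mice and re-isolated 7 days later. Total counts per library lay between 17484607 and 18355242, so 3 counts correspond to 0.163 to 0.172 CPM (counts scaled to a common library total) before scaling, and depth differed little between libraries. Of 21923 genes in the table, 12364 had enough counts to be tested. Levels below are CPM scaled by TMM, given as mean ± SD over n = 3 libraries. Log2 fold changes are given ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

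The Vivo libraries separated from both cultured groups along the first principal component, which held 47.5% of the variance of log2 CPM. The second component, with 18.2%, ran from Con replicates 1 and 3 to Vitro replicates 2 and 3, and Con replicate 2 and Vitro replicate 1 lay between them. The third component, with 13.9%, set Vivo replicate 3 apart from Vivo replicates 1 and 2. Vivo replicate 3 correlated with the other Vivo libraries at r = 0.949 and r = 0.951 across genes, against 0.970 to 0.986 for the other replicate pairs. Its deviation from the other Vivo libraries followed gene length (Spearman's rho = -0.52 across genes, which are not independent replicates). Mitochondrially encoded genes took 3.48% of its counts (95% Wilson interval 3.47 to 3.49), against 2.07% to 2.54% in the other 8 libraries. These intervals, like the count floors, cover counting error only.

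**Figure D1:**
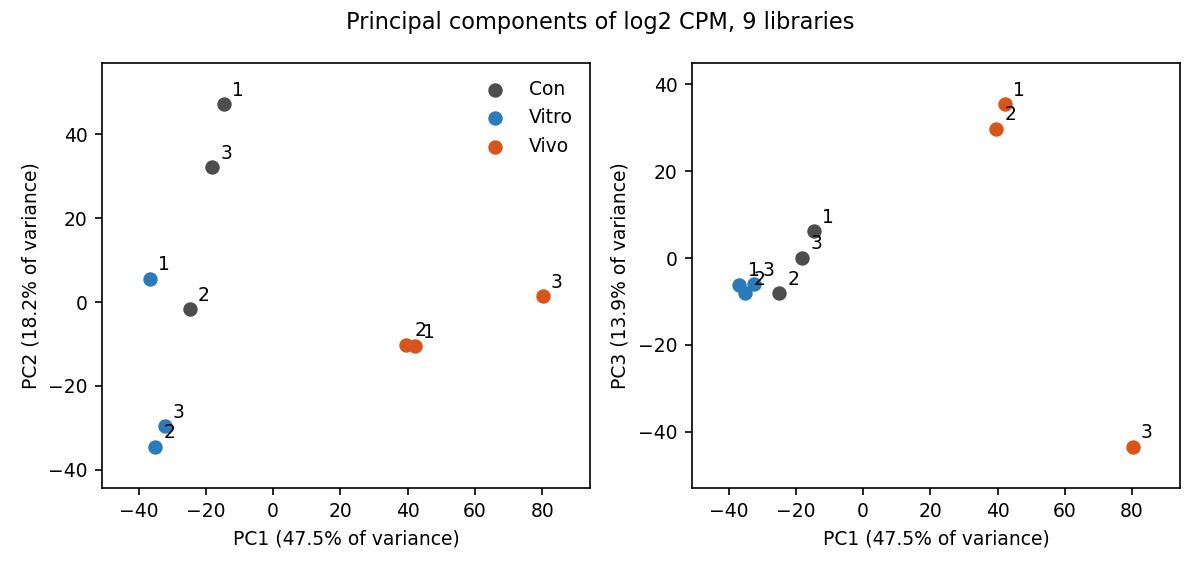
Each point is a library placed by principal components of log2 CPM (PC1 against PC2 on the left, PC1 against PC3 on the right; the axis labels give the percent of variance), coloured by group and numbered by replicate. The 3 Vivo libraries lie to the right of all 6 cultured libraries on PC1, and Vivo replicate 3 lies apart from Vivo replicates 1 and 2 on PC3.

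The comparison of Vivo with Con asks how the transcriptome of passage 4 cells differed after 7 days in host fat from that of the starting culture. Elastin and members of the Notch, immediate early and interferon lists were higher after re-isolation, while part of the adipogenic, cholesterol synthesis and contractile lists was lower. Camera, a test of a list against the other genes, called these 6 lists with its preset correlation and none of the 6 with an estimated one. Eln (ENSRNOG00000001469), which encodes elastin, rose from 1.33 ± 0.769 CPM in Con to 519.7 ± 216 in Vivo. Heyl (ENSRNOG00000015318), a transcriptional repressor induced by Notch, rose from 0.247 ± 0.0856 to 34.7 ± 8.29, and Nkd2 (ENSRNOG00000016103), an inhibitor of Wnt signalling, fell from 84.1 ± 10.6 to 9.04 ± 0.436. In all, 1203 of 12364 genes passed an adjusted p of 0.05, 639 of them higher in Vivo and 564 lower, and 708 changed at least 2-fold. The libraries of the 2 groups did not overlap for 4140 genes (33.5%, where chance gives 10%).

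Among the 8 largest rises named by the fixed rule, C7 (ENSRNOG00000061379), a component of the complement membrane attack complex, had no count in any Con or Vitro library and 18.9 ± 7.87 CPM in Vivo, at least 331-fold higher with 3 counts over the group as the floor. Trh, the precursor of thyrotropin-releasing hormone, rose by 7.30 ± 0.58 on the log2 scale (adjusted p = 2.3e-04). Eln rose by 8.60 ± 0.50 (adjusted p = 5.2e-05) and Fosb by 6.74 ± 0.56 (adjusted p = 2.3e-04). For 3 further genes, the Wnt modulator Dkk2 among them, the 3 Con libraries held 3 counts in all: the ratio of Vivo to Con was 147 (95% counting interval 50.03 to 716) for the matrix metalloproteinase Mmp10 and 131 (95% counting interval 44.4 to 636) for the aldehyde dehydrogenase Aldh3a1. The largest falls included Bmx, a Tec family tyrosine kinase (-5.15 ± 0.61), the metalloproteinase Pappa2 (-4.04 ± 0.53), and Ch25h, which hydroxylates cholesterol (-3.82 ± 0.46). Rassf4 fell from 84.9 ± 27.0 to 6.11 ± 1.19 CPM and the gap junction gene Gja5 from 41.6 ± 23.2 to 3.23 ± 1.80. The rule chose genes whose libraries did not overlap between the 2 groups.

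The Notch pathway list had the largest median shift of the 27 lists tested in this comparison. Of its 9 measured members 7 rose and none fell, and the count was also 7 adjusted over the list alone. Hes1 rose from 5.21 ± 1.63 to 126 ± 48.3 CPM. Hey1 had no count in Con and 1.34 ± 0.219 CPM in Vivo, at least 23.6-fold higher. Notch3 rose by 3.17 ± 0.63 (adjusted p = 0.016), and its call was lost without Con replicate 3 or Vivo replicate 1, where the adjusted p was up to 0.0756. Camera gave an adjusted p = 2.6e-07, and adjusted p = 0.066 with an estimated correlation. The deposited annotation, tested after seeing the data, holds a wider Notch signaling set, which camera did not call: 6 of its 36 genes rose, none fell and the median was 0.05 (adjusted p = 0.32).

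Genes of the immediate early list, which cells transcribe within minutes of stimulation or dissociation, rose in 13 of 18 measured members, with a median log2 change of 1.41. Fos rose from 8.63 ± 3.47 to 269 ± 130.2 CPM, Jun from 26.1 ± 1.16 to 231 ± 86.4 and Zfp36 from 52.7 ± 9.79 to 259.6 ± 86.1. Adjusted over the list alone the count was also 13. The camera call had an adjusted p = 2.0e-10, and adjusted p = 0.27 with an estimated correlation. In the interferon response list 10 of 22 measured members rose, 16 adjusted over the list alone, and none fell. Irf7, a transcription factor that amplifies interferon signalling, rose from 2.42 ± 0.480 to 18.4 ± 7.39 CPM, Bst2 from 0.975 ± 0.445 to 6.96 ± 2.86 and Oas1a from 0.460 ± 0.349 to 5.49 ± 3.03. Camera gave an adjusted p = 8.2e-09 for this list, and adjusted p = 0.26 with an estimated correlation.

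The cell cycle list was higher in Vivo than in Con, with a median log2 change of 1.00. Of 33 measured members 14 rose over all genes tested and 31 adjusted over the list alone. The replicative helicase genes Mcm2, Mcm3, Mcm5 and Mcm6 led the list with changes between 1.24 and 1.48. Each lost its call in 3 to 5 of the 6 fits that left out 1 library, always including those without Con replicate 1, Con replicate 3 or Vivo replicate 1, and the lowest changes in those fits were between 1.08 and 1.27 (adjusted p up to 0.146). Mki67 (0.85 ± 0.30, adjusted p = 0.098) and Cdk1 (0.78 ± 0.27, adjusted p = 0.10) did not pass, though Mki67 did without Vivo replicate 3 (adjusted p = 0.0343) and Cdk1 without Con replicate 2 (adjusted p = 0.0475). Both passed with DESeq2 (adjusted p = 0.0409 and 0.0491) and with sample quality weights (adjusted p = 0.0019 and 0.0183), and Mki67 with gene length offsets (adjusted p = 0.0160), the last 2 settings chosen after seeing the data. Over all alternatives the adjusted p reached 0.285 for Mki67 and 0.295 for Cdk1. Members of this list moved together across libraries, with an estimated correlation between genes of 0.84, and the camera call (adjusted p = 5.6e-12) was lost there, with adjusted p = 0.41 with an estimated correlation.

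Adipogenic genes were lower in Vivo: 4 of 14 measured members fell, none rose, and the count was also 4 adjusted over the list alone. Lpl, which encodes lipoprotein lipase, fell from 592 ± 178 to 118 ± 25.0 CPM and the lipid droplet gene Plin4 from 1.66 ± 0.171 to 0.183 ± 0.124. The insulin-responsive glucose transporter gene Slc2a4 fell by 2.61 ± 0.50 on the log2 scale, a call lost without Con replicate 3 (adjusted p = 0.0617). In the FPKM fit, chosen after seeing the data, neither Plin4 (adjusted p = 0.129) nor Slc2a4 (adjusted p = 0.0536) passed. Pparg, the master regulator of adipogenesis, was below the count filter, and Fabp4 averaged under 1 CPM in every group. Camera gave an adjusted p = 8.4e-04, and adjusted p = 0.27 with an estimated correlation. The cholesterol synthesis list fell on balance (camera adjusted p = 1.7e-05, and adjusted p = 0.39 with an estimated correlation). Of its 19 members 3 fell, and 13 fell adjusted over the list alone. Sc5d, a late enzyme of the pathway, fell by 0.85 ± 0.14 on the log2 scale.

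Genes of the osteogenic and chondrogenic lists moved both ways, and camera called neither list. In the osteogenic list 4 of 10 measured members fell and 1 rose, 4 and 2 adjusted over the list alone. Bmp2 fell from 4.06 ± 0.934 to 1.12 ± 0.112 CPM, and Sp7, a transcription factor of osteoblasts, fell from 7.15 ± 2.89 to 2.13 ± 0.514. In the chondrogenic list Sox9, its main transcription factor, fell from 41.2 ± 3.71 to 6.09 ± 1.60, and Prg4, which encodes the joint lubricant lubricin, rose from 1.26 ± 0.637 to 10.9 ± 3.18. Col11a2 fell by 2.71 ± 0.58 in the fit to all libraries, and was uncalled without Con replicate 1, Con replicate 3, Vivo replicate 1 or Vivo replicate 2 (adjusted p up to 0.080). Camera's adjusted p was 0.40 for the first list and 0.96 for the second, and adjusted over its list alone the chondrogenic count was 2 higher and 2 lower.

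Matrix and contractile genes also split. Of 31 extracellular matrix genes 5 rose and 7 fell, 7 and 11 adjusted over the list alone, and the list had a median of -0.30 and a mean of 0.25, which differ in sign (camera adjusted p = 0.55). Postn, which encodes periostin, rose from 184 ± 61.8 to 1125 ± 91.9 CPM and Col5a3 from 64.3 ± 8.68 to 614 ± 153, while Col1a1 was at 36196 ± 1799 in Con and 26197 ± 252 in Vivo (adjusted p = 0.15, and 0.0153 with sample quality weights). In the contractile list 4 of 15 measured members fell and 2 rose, with 8 lower and 2 higher adjusted over the list alone. The smooth muscle genes Cnn1 and Lmod1 fell by 1.57 ± 0.29 and 1.31 ± 0.18 on the log2 scale, and Acta2 stood at 1061 ± 175 CPM in Con and 719 ± 358 in Vivo (adjusted p = 0.31, 0.0267 without Vivo replicate 3 and 0.0036 with sample quality weights). Camera gave an adjusted p = 0.0074 for the contractile list, and adjusted p = 0.41 with an estimated correlation.

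Stromal surface markers moved both ways. Cd34, which is usually lost when ADSCs are cultured, rose from 0.323 ± 0.117 to 6.57 ± 0.377 CPM, Dpp4 from 0.210 ± 0.0346 to 3.11 ± 0.916 and Pi16 from 3.92 ± 0.495 to 14.7 ± 5.42. Alcam fell by 1.59 ± 0.26 on the log2 scale. Of 18 measured members 3 rose and 3 fell, 4 and 3 adjusted over the list alone, and camera's adjusted p was 0.89. Thy1 (-0.13 ± 0.19), Cd44 (0.22 ± 0.21), Nt5e (-0.38 ± 0.32) and Pdgfra (-0.03 ± 0.24), the usual positive markers, did not pass in edgeR, and Runx2 and Eng had adjusted p = 0.50 and 0.059. Thy1 passed without Vivo replicate 3 (adjusted p = 0.0234) and with sample quality weights (adjusted p = 0.0108). Eng passed without Vivo replicate 1 (adjusted p = 0.0385), with DESeq2 (adjusted p = 0.0205), with the replicate number as a block (adjusted p = 0.0432), with sample quality weights (adjusted p = 0.0483) and in the FPKM fit (adjusted p = 0.0498). The pluripotency list held 3 measured genes: Myc rose from 85.0 ± 6.03 to 174 ± 47.2 CPM and Klf4 by 1.04 ± 0.22, a call lost without Con replicate 1, Con replicate 3 or Vivo replicate 2 (adjusted p up to 0.084). Nanog and Pou5f1 had 0 counts in all 9 libraries, which allows up to 0.172 CPM per library before scaling. The list count was 2 over all genes and adjusted over the list alone, and camera's adjusted p was 0.18.

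Secreted factors rose in part. Of 19 senescence-associated secreted factors 5 rose and 1 fell, 7 and 1 adjusted over the list alone, with camera adjusted p = 0.045, and adjusted p = 0.47 with an estimated correlation. That call was also lost with directional fry, with gene length offsets (adjusted p = 0.145) and without Con replicate 1, Vivo replicate 1 or Vivo replicate 3 (adjusted p up to 0.294). Mmp3, which encodes stromelysin-1, rose from 2.37 ± 1.68 to 104 ± 44.8 CPM and Igfbp5 from 4.77 ± 1.43 to 47.9 ± 21.2. Of 22 paracrine growth factors 4 rose and 2 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.91). The placental growth factor gene Pgf rose from 4.80 ± 0.867 to 22.8 ± 9.45, and Figf, which encodes VEGF-D, fell from 889 ± 218 to 302 ± 29.4. Among 11 measured Wnt targets 3 rose and 3 fell, 4 and 3 adjusted over the list alone (camera adjusted p = 0.89). Sfrp2 rose from 13.6 ± 2.53 to 143 ± 59.2. In the NF-kB list 3 of 16 rose and 2 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.27), and Nfkbia, the feedback inhibitor of NF-kB, rose from 19.2 ± 10.1 to 133 ± 66.7.

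Few members of the metabolic and cell cycle inhibitor lists passed. Of 24 hypoxia and glycolysis genes 1 rose and 3 fell, also adjusted over the list alone, and Car9, a carbonic anhydrase induced by hypoxia, fell from 16.7 ± 2.99 to 7.69 ± 2.18 CPM (camera adjusted p = 0.14, called only without Vivo replicate 3 among the 6 fits that left out 1 library, with adjusted p = 0.0372). In the oxidative phosphorylation list 1 of 19 rose over all genes and adjusted over the list alone. Its camera call (adjusted p = 0.0074, and adjusted p = 0.45 with an estimated correlation) was lost with fry and without Vivo replicate 3 (adjusted p = 0.20). Of 11 mitochondrially encoded genes 1 rose, 3 adjusted over the list alone (camera adjusted p = 0.17). In edgeR none of the 6 measured CDK inhibitors passed over all genes or adjusted over the list alone, though 3 had an unadjusted p under 0.05 and 2 were higher with DESeq2 and 2 with sample quality weights (camera adjusted p = 0.32). Besides the matrix list, the median and mean differed in sign for the stromal, osteogenic, chondrogenic, growth factor, Wnt target and mesothelial lists. Directional fry called the stromal, pluripotency and mitochondrially encoded lists higher, which camera did not (adjusted p = 0.033, 0.010 and 0.048). The count of 1203 genes depended on single libraries: it was 462 without Con replicate 1, 341 without Con replicate 3, 667 without Vivo replicate 1, 747 without Vivo replicate 2 and 1706 without Vivo replicate 3, which kept 1051 of the 1203. More genes were lower than higher without Con replicate 1 (198 higher and 264 lower), Con replicate 3 (157 and 184) or Vivo replicate 3 (809 and 897), so which direction held more genes was not stable. It was 667 in a fit to the Vivo and Con libraries alone, 2087 with DESeq2 and 3458 with sample quality weights in limma, the last chosen after seeing the data.

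**Figure D2:**
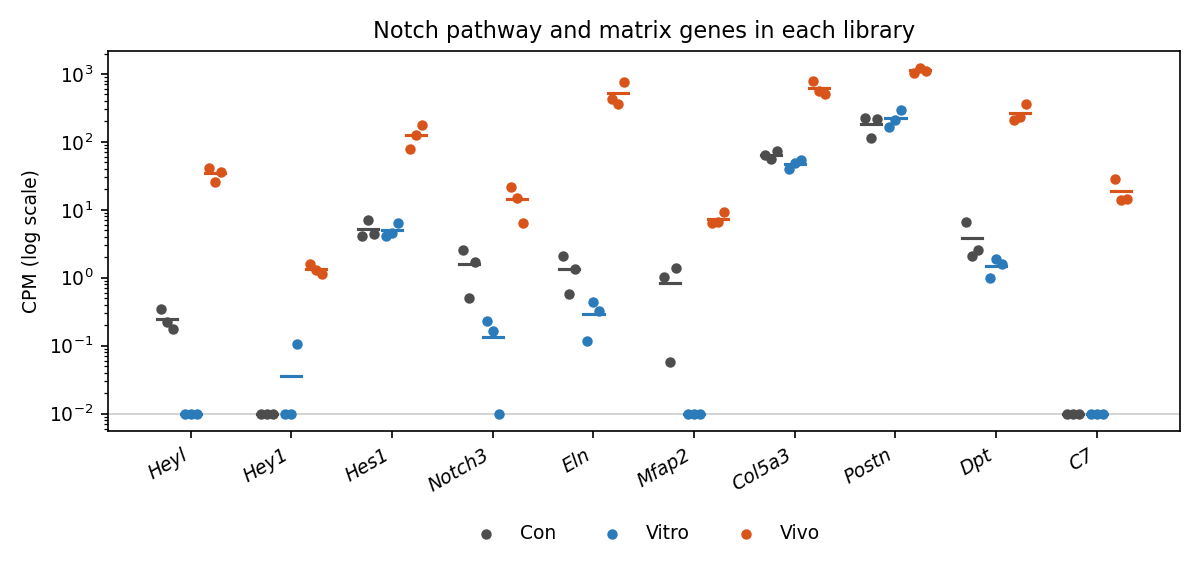
Level of 10 genes of the Notch pathway and extracellular matrix in each of the 9 libraries, in CPM on a log scale; points are libraries, bars are group means, and values under 0.01 CPM are drawn at 0.01. For each gene the 3 Vivo libraries lie above all Con and Vitro libraries; Eln, for example, averages 520 CPM in Vivo and 1.33 in Con.

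The comparison of Vivo with Vitro sets cells kept in host fat against cells kept in culture until the same time point. Against both cultured groups 724 genes passed, and all 724 went the same way, 341 higher and 383 lower in Vivo. Both comparisons use the Vivo libraries, which favours the same sign. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.816, against 0.494 ± 0.013 (SD over 20 simulations) for unchanged groups set against shared libraries, where no gene was called in both. The simulation gave every group the same spread for a gene, while Vivo replicate 3 stood apart from the other Vivo libraries. A larger spread in the shared Vivo libraries raises the correlation by itself, so 0.494 may be too low for these data. Heyl and the microfibril gene Mfap2 had no count in Vitro and reached 34.7 ± 8.29 and 7.42 ± 1.64 CPM in Vivo, at least 629-fold and 134-fold higher. The matrix gene Dpt, which encodes dermatopontin, rose from 1.49 ± 0.459 to 269 ± 83.8, and Myocd, the coactivator of smooth muscle genes, fell from 5.93 ± 0.532 to 0.312 ± 0.109. In all 1348 genes passed, 665 higher and 683 lower in Vivo, and 868 changed at least 2-fold. The libraries did not overlap for 4356 genes (35.2%, where chance gives 10%).

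Other genes named by the rule were Itm2a (7.00 ± 0.64, adjusted p = 2.5e-04) and Eln (10.76 ± 0.57, adjusted p = 2.0e-05), both higher in Vivo. Ptprb, a receptor tyrosine phosphatase best known from endothelium, fell from 14.5 ± 1.08 to 0.276 ± 0.0489 CPM, Pappa2 from 31.04 ± 6.35 to 0.533 ± 0.504 and Scube3 from 34.0 ± 14.5 to 1.81 ± 1.496. Dcdc2 fell by 4.26 ± 0.58 on the log2 scale, and Rassf4 from 112 ± 40.1 to 6.11 ± 1.19 CPM. The calls of these 7 genes held in each of the 6 fits that left out 1 library.

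In the Notch list 8 of 9 measured members rose, also 8 adjusted over the list alone, with a median log2 change of 3.68. Notch3 rose by 6.71 ± 0.84 and Hes1 by 4.65 ± 0.35. Hey1 had 2 counts in Vitro and 73 in Vivo, a ratio of 36.7 (95% counting interval 9.79 to 308). With Heyl at its floor in place of its fitted change the list median was still 3.68, and with Hey1 at its floor it was still 2.63 against Con. Of the 8 lists that camera called in this comparison, this one alone kept its call with an estimated correlation (adjusted p = 3.2e-09, and adjusted p = 0.034 with an estimated correlation). The deposited Notch annotation had 9 of its 36 genes higher and 2 lower, with a median of 0.10 (camera adjusted p = 0.085). In the immediate early list 14 of 18 members rose, 17 adjusted over the list alone, and Egr3 rose from 0.664 ± 0.166 to 13.9 ± 2.67 CPM (camera adjusted p = 2.8e-15, and adjusted p = 0.15 with an estimated correlation). In the interferon list 12 of 22 rose, 15 adjusted over the list alone, among them Oas1a (5.34 ± 0.72) and Bst2 (4.29 ± 0.50). Isg15 rose by 3.02 ± 0.60, a call lost without Vitro replicate 3 (adjusted p = 0.0582). The interferon list had a camera adjusted p = 3.2e-09, and adjusted p = 0.15 with an estimated correlation.

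**Figure D3:**
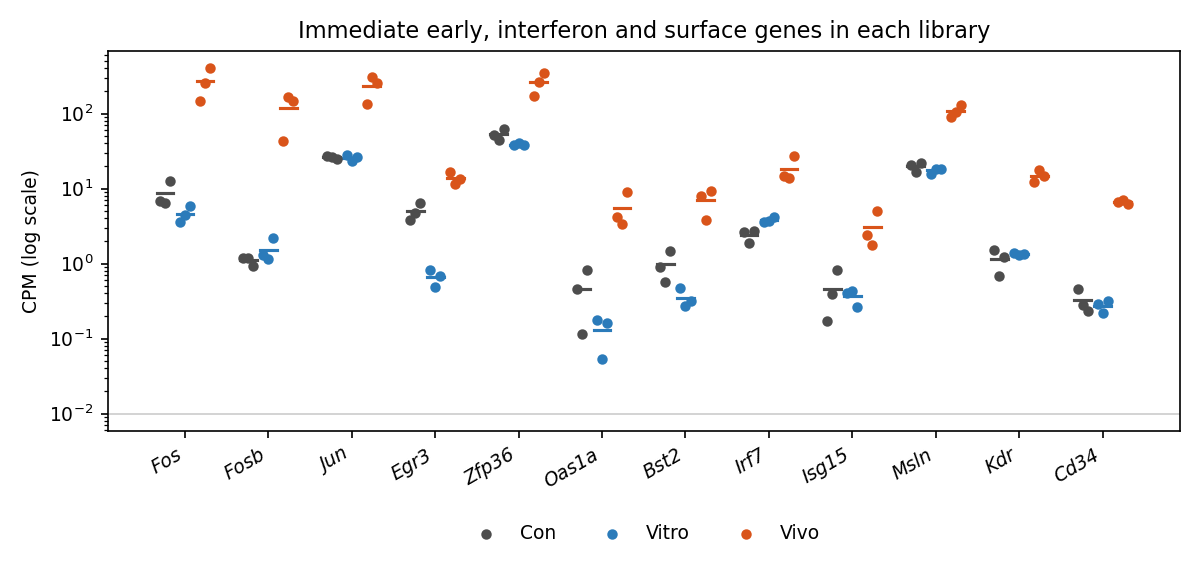
Level of 12 immediate early, interferon-stimulated and surface marker genes in each of the 9 libraries, in CPM on a log scale; points are libraries and bars are group means. The 3 Vivo libraries lie above all Con and Vitro libraries for each gene; Fos, for example, averages 269 CPM in Vivo and 8.63 in Con.

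Whether camera called the cell cycle list between Vivo and Vitro depended on the setting. Mki67 was at 259.7 ± 76.0 CPM in Vitro and 240.2 ± 75.3 in Vivo, and 1 of 33 members passed, Ccnd1, lower in Vivo, with none adjusted over the list alone. The Ccnd1 call (adjusted p = 0.044) was lost in 5 of the 6 fits that left out 1 library, all but that without Vitro replicate 1 (adjusted p up to 0.136), and in the FPKM fit (adjusted p = 0.0555). Camera's adjusted p was 0.056 with a median of 0.30. The list passed without Vitro replicate 2 or Vitro replicate 3 (adjusted p down to 0.0012), with the replicate number as a block (adjusted p = 0.0313) and with gene length offsets (adjusted p = 0.0273). Without Vitro replicate 1 the adjusted p was 0.986, and with an estimated correlation it was 0.77. Among the CDK inhibitors Cdkn1c, which encodes p57, rose from 0.707 ± 0.420 to 9.93 ± 2.22 CPM, and Cdkn1a, which encodes p21, fell from 136 ± 9.91 to 62.6 ± 12.1. Cdkn2b fell by 1.02 ± 0.26 on the log2 scale, uncalled without Vivo replicate 1 or any 1 Vitro library (adjusted p up to 0.13), in a fit to 2 groups alone (adjusted p = 0.0801) and with gene length offsets (adjusted p = 0.0985). The list count was 1 higher and 2 lower over all genes and adjusted over the list alone (camera adjusted p = 0.87).

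Contractile genes were also lower against Vitro: 8 of 15 fell and 2 rose, 11 and 2 adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, fell from 64.9 ± 40.2 to 9.77 ± 2.73 CPM and Cnn1 from 341 ± 70.4 to 68.7 ± 26.7, while Des, which encodes desmin, rose from 2.09 ± 0.698 to 9.58 ± 0.815. Camera gave an adjusted p = 0.0014, and adjusted p = 0.40 with an estimated correlation. Of 31 matrix genes 8 rose and 4 fell, 11 and 6 adjusted over the list alone, and the median (-0.02) and mean (0.63) differed in sign (camera adjusted p = 0.34). Col5a3 rose by 3.69 ± 0.22 and Postn by 2.34 ± 0.28. In the osteogenic list 1 member rose and 4 of 10 fell, 2 and 4 adjusted over the list alone, and Bmp6 fell from 70.2 ± 12.0 to 12.4 ± 2.21 CPM (camera adjusted p = 0.030, and adjusted p = 0.31 with an estimated correlation). The osteogenic call was lost without Vivo replicate 2 or Vivo replicate 3 (adjusted p up to 0.126), with no filter (adjusted p = 0.288) and with gene length offsets (adjusted p = 0.0535). In the chondrogenic list Sox9 fell (adjusted p = 1.6e-04) and Prg4 rose by 3.71 ± 0.40, the list counts being 1 and 1 of 7, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.51).

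Among stromal markers 5 of 18 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.89). Cd34 rose from 0.275 ± 0.0532 to 6.57 ± 0.377 CPM and Eng, which encodes CD105, from 50.4 ± 2.03 to 131 ± 37.2, while Cd55 fell from 3035 ± 258 to 948 ± 332. Thy1 (adjusted p = 0.28), Runx2 (adjusted p = 0.092) and Acta2 (adjusted p = 0.19) passed only without Vivo replicate 3 among the 6 fits that left out 1 library, with adjusted p = 0.0044, 0.0102 and 0.0153. They also passed with sample quality weights, and Thy1 and Runx2 with gene length offsets (adjusted p = 0.0348 and 0.0131). Myc rose by 1.64 ± 0.19 and Klf4 by 1.19 ± 0.22, 2 of 3 pluripotency genes on either adjustment (camera adjusted p = 0.056). That list was called without Vitro replicate 3, Vivo replicate 1 or Vivo replicate 3 (adjusted p down to 0.0289), and with the replicate number as a block (adjusted p = 0.0480). In the secreted factor list 3 of 19 rose and 1 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.46). Igfbp5 rose by 4.34 ± 0.36, and the chemokine gene Ccl20 fell from 94.2 ± 4.199 to 19.4 ± 3.51. Of 22 growth factors 2 rose and 5 fell, 2 and 7 adjusted over the list alone (camera adjusted p = 0.36), and Igf1 rose from 0.880 ± 0.0733 to 5.77 ± 2.51. In the NF-kB list 1 of 16 rose and 2 fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.37), with the complement gene C3 falling by 3.13 ± 0.56 on the log2 scale.

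For Wnt targets 4 of 11 rose and 3 fell, 4 and 4 adjusted over the list alone (camera adjusted p = 0.51), with a median of -0.51 and a mean of 0.59. Nkd2 fell by 3.07 ± 0.23 on the log2 scale. The adipogenic list had 2 of 14 lower on either adjustment (camera adjusted p = 0.067), with Plin4 falling by 2.66 ± 0.53 on the log2 scale, a call lost in the FPKM fit (adjusted p = 0.136). In the cholesterol list 3 of 19 fell, 5 adjusted over the list alone (camera adjusted p = 0.0064, and adjusted p = 0.50 with an estimated correlation), a call lost with directional fry and without Vitro replicate 1 (adjusted p = 0.087). The hypoxia list had 1 higher and 3 lower of 24 on either adjustment (camera adjusted p = 0.54), and the vasodilator peptide gene Adm rose from 261 ± 22.9 to 501 ± 85.0 CPM. In the oxidative phosphorylation list 1 of 19 rose and none adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.61 with an estimated correlation), a call lost with fry, with gene length offsets (adjusted p = 0.178) and without Vitro replicate 2 or Vivo replicate 3 (adjusted p up to 0.193). Of 11 mitochondrially encoded genes 2 rose, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.41). Directional fry called the stromal, pluripotency and matrix lists higher and the adipogenic list lower, which camera did not (adjusted p = 0.0085, 0.0018, 0.047 and 0.038). The median and mean also differed in sign for the stromal, CDK inhibitor and mesothelial lists. More genes were higher than lower, against 665 and 683 with all libraries, without Vitro replicate 1 (480 and 466), Vivo replicate 1 (551 and 526) or Vivo replicate 2 (535 and 518). The count of 1348 genes was 661 without Vitro replicate 2, 689 without Vitro replicate 3, 861 in a fit to the Vivo and Vitro libraries alone, 2129 with DESeq2 and 2852 with sample quality weights.

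**Figure D4:**
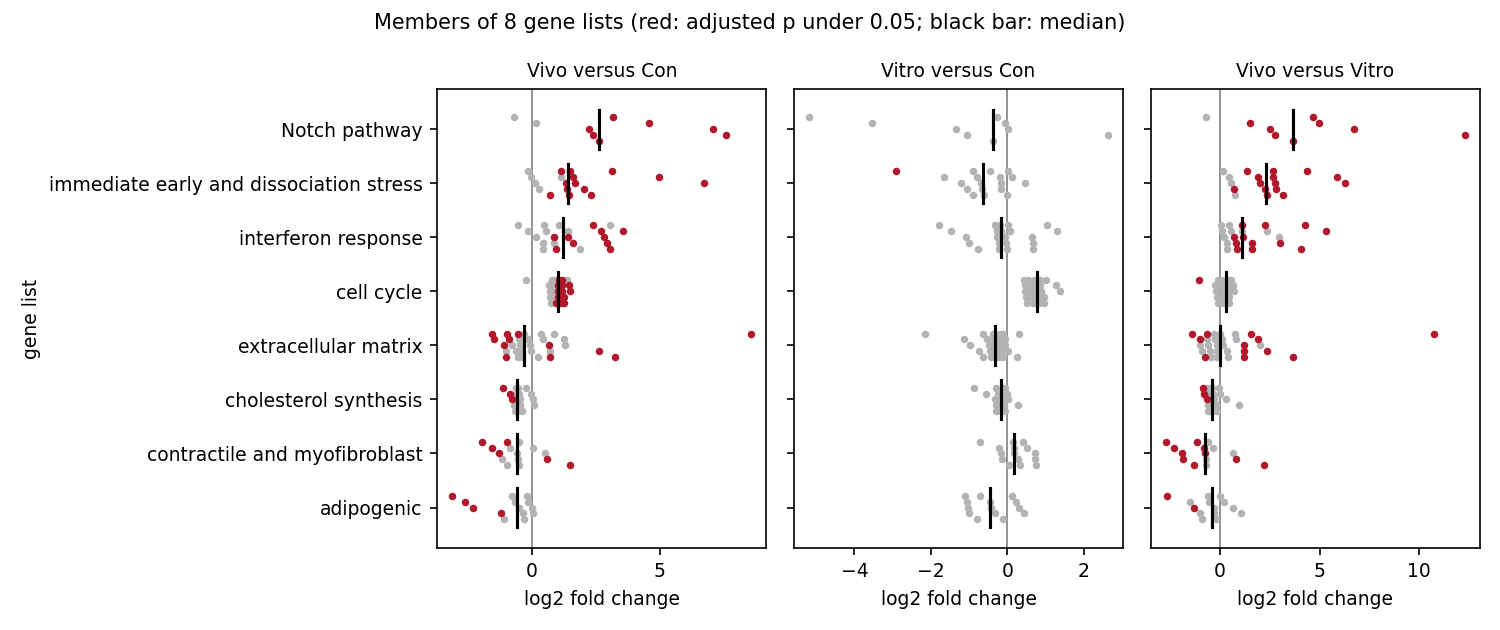
Log2 fold change (horizontal axis) of every measured member of 8 gene lists (vertical axis) in the 3 comparisons; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Notch pathway genes have a median of 2.63 against Con and 3.68 against Vitro, and cell cycle genes a median of 1.00 in Vivo and 0.78 in Vitro, each against Con.

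The comparison of Vitro with Con asks what continued culture alone changed. Few genes passed: Ptprb rose from 4.85 ± 0.375 to 14.5 ± 1.08 CPM, and the immediate early transcription factor gene Egr3 fell from 4.98 ± 1.33 to 0.664 ± 0.166. The other 2 calls, named here after their values were seen, were Dpysl4 (-3.28 ± 0.35) and LOC100910882 (-2.83 ± 0.30), both lower. The 4 genes had adjusted p-values between 0.014 and 0.019, and 1405 of 12364 genes had an unadjusted p under 0.05 in edgeR. The libraries did not overlap for 2643 genes (21.4%, where chance gives 10%). Ptprb lost its call without Con replicate 1, Con replicate 3 or any 1 Vitro library (adjusted p up to 0.208), and Egr3 without Con replicate 1, Con replicate 3, Vitro replicate 2 or Vitro replicate 3 (adjusted p up to 0.138) and in the FPKM fit (adjusted p = 0.163). The count was 0 without Con replicate 1, without Con replicate 3, without Vitro replicate 3 and in a fit to these 6 libraries alone, 1 without Vitro replicate 2 and 54 without Con replicate 2. It was 299 with DESeq2 and 2690 with sample quality weights.

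Camera called 12 of 27 lists in this comparison, and none of the 12 passed with an estimated correlation or with directional fry. Mixed fry, which counts changes in either direction, called the osteogenic, Notch and immediate early lists (adjusted p = 7.8e-04 each). It also called the secreted factor and growth factor (0.029 each) and adipogenic and NF-kB lists (0.049 each). It did not call the cell cycle, matrix, hypoxia, cholesterol synthesis or epithelial lists (adjusted p between 0.069 and 0.40). Cell cycle genes were higher in Vitro by a median of 0.78, with 0 of 33 past the threshold over all genes in edgeR, 26 at an unadjusted p under 0.05, 1 with DESeq2, 33 with sample quality weights and 25 in edgeR adjusted over the list alone (camera adjusted p = 1.7e-15, and adjusted p = 0.33 with an estimated correlation). Mki67 was at 133 ± 34.6 CPM in Con and 259.7 ± 76.0 in Vitro. Immediate early genes were lower, with a median of -0.63 with 7 of 18 lower adjusted over the list alone (camera adjusted p = 2.3e-06, and adjusted p = 0.33 with an estimated correlation). Matrix genes were lower, with a median of -0.32, with 5 of 31 lower adjusted over the list alone (camera adjusted p = 1.7e-05, and adjusted p = 0.33 with an estimated correlation). For Notch genes the median was -0.36 with 4 of 9 lower adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.26 with an estimated correlation). NF-kB genes were higher by a median of 0.55, with 2 of 16 adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.33 with an estimated correlation).

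Camera also called lists with higher medians for osteogenic (0.32, 4 of 10 adjusted over the list alone), secreted factor (0.36, 4 of 19) and growth factor genes (0.23, 2 of 22 higher and 1 lower). Lower medians were found for adipogenic (-0.45, 1 of 14), hypoxia (-0.22, 1 of 24) and cholesterol synthesis genes (-0.16, 0 of 19). Camera gave these 6 adjusted p = 0.034, 0.012, 0.038, 0.020, 0.0019 and 0.034 in that order. With an estimated correlation these 6 had adjusted p = 0.33, 0.42, 0.33, 0.33, 0.37 and 0.56 in that order. The secreted factor call was lost without Con replicate 1, the osteogenic and growth factor calls without Con replicate 1 or Vitro replicate 1 and with gene length offsets (adjusted p = 0.0624 and 0.0532), the osteogenic call with the replicate number as a block (adjusted p = 0.0671), and the cholesterol call (1 gene at an unadjusted p under 0.05, 0 with DESeq2 and 1 higher and 4 lower with sample quality weights) without Con replicate 1, Con replicate 2, Vitro replicate 2 or Vitro replicate 3, where the adjusted p reached 0.299. Among the lists with no camera call, 3 of 6 CDK inhibitors were higher and 1 lower adjusted over the list alone, and Cdkn1a was at 72.7 ± 12.6 CPM in Con and 136 ± 9.91 in Vitro (adjusted p = 0.18, 0.0014 with DESeq2 and 0.0027 with sample quality weights). For the stromal, chondrogenic, contractile, interferon, oxidative phosphorylation and mitochondrially encoded lists no member passed in edgeR on either adjustment, and none with DESeq2. At an unadjusted p under 0.05 these 6 lists had 4, 1, 4, 3, 0 and 0 genes, and sample quality weights called 5, 2, 5, 2, 0 and 2. In edgeR 1 of 3 pluripotency genes was lower, and 1 of 11 Wnt targets was higher and 2 lower, adjusted over the list alone. The median and mean differed in sign for the stromal, oxidative phosphorylation, Wnt target and Schwann cell lists. Camera called the contractile list without Vitro replicate 2 (adjusted p = 0.0077) and the pluripotency list without Vitro replicate 3 (adjusted p = 0.0392).

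The changes of the Vivo and Vitro groups against the same Con libraries were also set side by side. LOC100910882 fell in both and was the 1 gene called the same way, while Egr3 and Ptprb were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.106, against 0.503 ± 0.011 (SD over 20 simulations) for unchanged groups set against shared controls. The covariance was 0.0465 against 0.0605 ± 0.0024 in the simulations, and independent lists of these sizes would share 0.052 higher and 0.137 lower genes. Both values lie below the simulated ones. The simulation gave every group the same spread for a gene, from a fit that included Vivo replicate 3. Its covariance may therefore be too high for the Con libraries, so an excess over shared controls stays undecided. The correlation cannot decide this, since a change in Vivo alone lowers it. Genes were simulated independently, so the SDs leave out the spread from genes that move together. The Con libraries are too few to be split. A test of any difference among the 3 groups called 1242 genes. That count was 764 without Con replicate 1, 633 without Con replicate 3, 639 without Vitro replicate 2, 669 without Vitro replicate 3, 765 without Vivo replicate 1, 736 without Vivo replicate 2 and 1824 without Vivo replicate 3. The number of genes called the same way in both comparisons was 0 without Con replicate 1 or Con replicate 3 and 15 without Con replicate 2.

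Most markers of leukocytes and red cells were low in all groups, with Cd14 an exception, while single endothelial, pericyte, mesothelial, muscle and Schwann cell markers moved with the Vivo group. The leukocyte marker Ptprc was below the count filter, with 0.0566 ± 0.0980 CPM in Con, 0 in Vitro and 0.0372 ± 0.0322 in Vivo. Of the macrophage markers 3 of 19 could be tested and none passed over all genes in edgeR. With sample quality weights 1 was higher against Con and 1 against Vitro, and with DESeq2 1 against Con. Cd14 was at 20.6 ± 1.62 CPM in Con, 21.2 ± 3.19 in Vitro and 23.8 ± 1.66 in Vivo. In Vivo against Con 1 macrophage marker was higher adjusted over the list alone. Camera gave the macrophage list an adjusted p = 0.12 against Con and 0.21 against Vitro. It called the list higher than in Vitro with no filter (median 1.72, adjusted p = 0.0175, and adjusted p = 0.10 against Con), and directional fry, which tests a list without the other genes, called it higher against both (adjusted p = 0.0103 and 0.0302). No neutrophil or erythroid marker passed the count filter, and 1 lymphocyte gene (Gzmb), 1 mast cell gene (Kit) and 2 class II antigen presentation genes did. In edgeR Gzmb was higher in Vivo than Vitro, and Kit lower in Vitro than Con, at an unadjusted p under 0.05. Neither passed over all genes (adjusted p = 0.065 and 0.34). Gzmb passed with DESeq2 (adjusted p = 0.0070) and Kit with sample quality weights (adjusted p = 0.0366). Of the class II genes Ciita fell against Vitro by 3.16 ± 0.74 on the log2 scale. That call was lost without Vitro replicate 2, Vitro replicate 3 or Vivo replicate 2 (adjusted p up to 0.084). It was also lost in a fit to 2 groups alone (adjusted p = 0.0570). Of 4 measured endothelial markers Kdr, which encodes VEGF receptor 2, rose from 1.14 ± 0.433 in Con to 14.8 ± 2.66 CPM in Vivo, and Tek, Flt1 and Egfl7 did not pass against Con in edgeR, where 2 of the 4 had an unadjusted p under 0.05. DESeq2 called 1 of the 4 higher, and sample quality weights called 2 higher and 1 lower (camera adjusted p = 0.15). Cdh5 and Vwf were below the count filter. Against Vitro Kdr rose by 3.46 ± 0.30 and Flt1 fell by 1.18 ± 0.30 on the log2 scale, the latter lost without Vitro replicate 2, Vitro replicate 3, Vivo replicate 1 or Vivo replicate 3 (adjusted p up to 0.13), in a fit to 2 groups alone (adjusted p = 0.0510) and in the FPKM fit (adjusted p = 0.0502). Camera gave the endothelial list an adjusted p = 0.42 against Vitro, while directional fry called it higher in Vivo against both groups (adjusted p = 0.0013 and 0.0042). Adjusted over the list alone 1 endothelial gene was higher in Vivo than Con, 1 in Vitro than Con, and 1 was higher and 1 lower in Vivo than Vitro.

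Pericyte markers went both ways. Cspg4, which encodes NG2, rose against Con by 1.70 ± 0.29, a call lost without Con replicate 3 (adjusted p = 0.0511), and Ndufa4l2 fell from 90.8 ± 16.1 to 24.9 ± 9.62 CPM. Against Vitro the potassium channel genes Kcnj8 (3.86 ± 0.61) and Abcc9 (2.66 ± 0.44) rose, and Ndufa4l2 fell by 1.47 ± 0.29 on the log2 scale. Adjusted over the list alone 4 of 6 were higher and 1 lower against Con, and 3 and 1 against Vitro (camera adjusted p = 0.15 and 0.064, the latter passing without Vivo replicate 2 at 0.0478 and with the replicate number as a block at 0.0313). In Vitro against Con 1 was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.052), a list called without Con replicate 2, Con replicate 3 or Vitro replicate 1 (adjusted p down to 0.0273), and also with either other filter or the replicate number as a block (adjusted p between 0.0102 and 0.04998). Of the mesothelial markers Msln, which encodes mesothelin, rose from 19.8 ± 2.79 in Con to 108 ± 20.7 CPM in Vivo, and Wt1 rose by 1.12 ± 0.22 against Con, a call lost without Con replicate 3 (adjusted p = 0.0767). Camera's adjusted p for the mesothelial list was 0.40 against Con and 0.42 against Vitro, with 2 higher and 1 lower adjusted over the list alone in each. The 3 measured epithelial markers, Krt8, Krt18 and Elf5, stayed under 5 CPM in every group and rose against Vitro, where camera gave an adjusted p = 0.0045, and adjusted p = 0.19 with an estimated correlation. They were lower in Vitro than in Con adjusted over the list alone (camera adjusted p = 9.2e-04, and adjusted p = 0.26 with an estimated correlation). Krt18 lost its call against Vitro in the FPKM fit (adjusted p = 0.0503) and in 4 and Krt8 in 2 of the 6 fits without 1 library, those without Vitro replicate 1 and Vitro replicate 3 among them (adjusted p up to 0.104 and 0.0631). Against Con camera called the epithelial list only without Con replicate 1 (adjusted p = 0.0249). The muscle marker Acta1 fell from 4.81 ± 1.42 in Con to 0.983 ± 0.449 CPM in Vivo, and the Schwann cell marker S100b from 45.4 ± 10.3 to 12.9 ± 1.98 (camera adjusted p = 0.20 and 0.094, the Schwann list passing without Con replicate 2 at 0.0314). Directional fry called further marker lists against both Con and Vitro: the mesothelial list higher (adjusted p = 4.9e-04 and 2.3e-04), and the muscle list (adjusted p = 0.010 and 0.0014) and the Schwann cell list (adjusted p = 0.0085 and 0.012) lower. It called the pericyte list higher against Vitro (adjusted p = 0.012, and 0.097 against Con).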

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

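Sample quality weights, gene length offsets and the FPKM fit were chosen after seeing the data. For Vivo against Con, Vitro against Con, Vivo against Vitro and any difference among the groups, the counts of 1203, 4, 1348 and 1242 genes became 2087, 299, 2129 and 2633 with DESeq2, which gave no adjusted p for 19 genes in each pairwise comparison, and 3458, 2690, 2852 and 4946 with sample quality weights. A minimum change of 2-fold left 708, 4 and 868, and fits to 2 groups alone gave 667, 0 and 861, with fewer libraries to estimate the spread. The cause of the other differences was not tested. With 1 library left out the counts ran from 341 to 1706, from 0 to 54, from 661 to 1660 and from 633 to 1824, and, with 1 Con library left out, the number of genes called the same way in both comparisons against Con from 0 to 15 (1 with all libraries). For a pair of groups only libraries of those 2 groups were left out. The range for Vitro against Con therefore holds no fit without Vivo replicate 3, which shared in estimating the spread. DESeq2-style size factors, either other filter, length offsets and the FPKM fit left these 4 counts within 1.5 times. The median log2 fold change over all genes moved by under 0.1 in each comparison with the size factors and with length offsets. In the FPKM fit, 806 of 1210 genes were higher and 404 lower for Vivo against Con (66.6% higher, against 53.1%). The pseudocount alternative was not run, as counts were deposited.

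The replicate number as a block gave 1203, 7, 1243 and 1249 genes, of which 1013, 4, 1122 and 1032 were among those called without it. Correlations of same-numbered deviations were 0.0563, 0.0573 and 0.0278 for Vivo with Con and 0.358, 0.324 and 0.0921 for Vitro with Con. They were 0.0252, 0.112 and -0.0150 for Vivo with Vitro. No value expected without pairing was computed, so whether the numbers pair the libraries stays open. Every library correlated best with its own number for Vivo with Con, but not for the other pairs.

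No gene named by the rule, and no list, changed from a call in one direction to a call in the other. Over all alternatives genes named by the rule kept their side of the threshold 3364 times, lost a call 245 times and gained one 47 times, and lists did so 984, 77 and 73 times. Among these list results mixed fry gained 33 calls and lost 8, and directional fry gained 18 and lost 16. Depth limits what can be said of genes under 0.172 CPM per library.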

Other observations

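The deposited pathway annotation, tested after seeing the data, held groups that the fixed lists did not, and a Notch signaling set of 36 genes that was called in none of the 3 comparisons. For Vivo against Con 27 of 251 pathways of 15 to 300 genes were called, 20 of them higher, for Vitro against Con 10, 7 higher, and for Vivo against Vitro 18, 9 higher. None was called with an estimated correlation. DNA replication genes were higher in Vivo than Con by a median of 1.15, with 19 of 33 called higher (adjusted p = 7.4e-09, and adjusted p = 0.59 with an estimated correlation). They were also higher in Vitro than Con by a median of 0.54 with no member called by edgeR (adjusted p = 3.2e-07, and adjusted p = 0.97 with an estimated correlation). Spliceosome genes (12 of 113 higher, adjusted p = 1.1e-06) and proteasome genes (7 of 39, adjusted p = 1.6e-05) were higher in Vivo than Con, with adjusted p = 0.59 and 0.71 with an estimated correlation.

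Ribosome genes were higher in Vivo than Vitro by a median of 0.45, with 4 of 112 called (adjusted p = 4.1e-08, and adjusted p = 0.81 with an estimated correlation). Antigen processing and presentation genes had 11 of 40 higher against Con and 11 higher and 2 lower against Vitro (adjusted p = 7.3e-04 and 0.0013, and adjusted p = 0.59 and 0.80 with an estimated correlation). Actin cytoskeleton regulators had 18 of 146 lower and 5 higher in Vivo than Vitro (adjusted p = 0.0049, and adjusted p = 0.80 with an estimated correlation).

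The test of the immediate early genes was chosen after the result was seen, as were part of the condition for pericytes and the gene lengths used for Heyl and Hey1. The length offsets used for Notch pathway genes and elastin were also chosen after seeing the data. Genes higher in Vivo than Con could come from host cells carried over at re-isolation. The tables argue against host macrophages and endothelial cells as the source of the raised genes as a whole: the median over the macrophage markers of the mean Vivo level was 0.183 CPM, and over the endothelial markers 0.228 CPM, the highest being Cd14 at 23.8 and Egfl7 at 27.4, which stood at 20.6 and 34.0 in Con. A small admixture stays open. Camera called the macrophage list higher in Vivo than Vitro with no filter (median 1.72, adjusted p = 0.0175), and directional fry called the macrophage list (adjusted p = 0.0103 and 0.0302) and the endothelial list (adjusted p = 0.0013 and 0.0042) higher against Con and Vitro, but it also called the mesothelial list higher and the muscle and Schwann cell lists lower against both. Kdr rose from 1.14 to 14.8 CPM, the macrophage median was 0.0566 in Con, and, in markers chosen after their values were seen, counts summed over 3 libraries went from 3 in Con to 29 in Vivo for Spi1, 0 to 10 for Tyrobp, 8 to 30 for Mrc1 and 2 to 15 for Cybb. Single libraries carried much of these sums (14, 8, 23 and 15 counts in 1 library), and in the same list Ptprc went from 3 to 2, Laptm5 from 4 to 3, C1qb from 2 to 0 and Aif1 stayed at 2. The sources used here do not say whether re-isolated cells were sorted on GFP or whether mouse reads were removed. How many mouse reads of each gene align to the rat genome was not tested, so the argument holds only if markers lose no more of them than the raised genes do. Host cells of other types, stromal cells of the fat among them, were not tested as a source of the raised genes as a whole and stay open. A response of the rat cells to the host tissue also stays open and was not tested.

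For Notch pathway genes and elastin a gene length trend and host pericytes were weighed. The tables argue against the length trend as the whole cause, since the median log2 change of Eln, Heyl, Hey1 and Notch3 was 7.35 after the trend was removed, and 5.80 with Hey1 at its floor. Heyl and Hey1 had too few counts in Con for an implied length, so theirs came from all libraries. Heyl went from 7.09 to 7.17, Hey1 from 7.60 to 7.54, Eln from 8.60 to 8.66 and Notch3 from 3.17 to 3.25, and each passed afterwards (adjusted p up to 0.0080). Pericyte markers without Notch3 had a median of 18.5 CPM in Vivo and 8.11 in Con, which met the condition set beforehand for pericytes as the cause (at least 5 CPM and above Con). A further condition, that no marker be called lower, was added after the values were seen: Cspg4 rose while Ndufa4l2 fell, Rgs5 had 18 counts over the 3 Vivo libraries, and Cox4i2 was at 48.5 in Vivo and 47.2 in Con. Adjusted over the list alone, Notch3 included, 4 of 6 measured markers were higher and 1 lower against Con, and 3 and 1 against Vitro. Ndufa4l2 was expressed in the cultured Con cells, so its fall does not exclude added pericytes. Host pericytes and a Notch response of the injected cells cannot be told apart here, and the latter was not tested.

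Immediate early genes were higher in Vivo than in both cultured groups, with medians of 1.41 against Con and 2.30 against Vitro. Every Vivo library and no other was re-isolated from tissue, so transcription during re-isolation and a response to 7 days in the host cannot be told apart.

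Among the 10 splits of the 6 libraries of a pair of groups, the real one gave 1203 genes for Vivo against Con (highest other 0), 4 for Vitro against Con (highest other 0) and 1348 for Vivo against Vitro (highest other 1), and each was the 1 split with as many genes. These splits are too few for a share under 0.05. For the 3 groups the real split gave 1242 genes and 1 of 100 splits, the real one, gave as many, the highest other giving 526. This argues against a chance arrangement of the libraries only if they are independent, which the labels do not say.

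Vivo replicate 3 had a sample quality weight of 0.0942. Gene length was implied by counts and FPKM for 98.6% of the tested genes. It was correlated with each library's deviation from the mean of the other libraries of its group, across genes, which are not independent replicates. Spearman's rho was 0.41 in Vivo replicate 1, 0.45 in Vivo replicate 2 and -0.52 in Vivo replicate 3, and within 0.1 of 0 in the other 6 libraries. The means for Vivo replicates 1 and 2 include Vivo replicate 3, so their values may mirror its deviation. After each library's trend with gene length was removed Vivo replicate 3 correlated with the other Vivo libraries at r = 0.958 and r = 0.961. Of the 1203 and 1348 genes called for Vivo against Con and against Vitro, 1051 and 1155 were also called without it, and all 1203 and 1348 kept their sign.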
